A study of Schizosaccharomyces pombe with 36 samples.

How the data were processed

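RNA of the fission yeast Schizosaccharomyces pombe was sequenced from wild-type (WT) cells and from cells in which slr1, which encodes a La-related protein of the LARP1 family, had been knocked out. Per the labels, 3 cultures of each genotype were grown from single colonies, given the uridine analogue 4-thiouracil, and sampled repeatedly. From each culture 1 library of unselected RNA, called steady state, and 5 libraries of RNA pulled down through the incorporated thiol groups, called labelled 5, 20, 50, 105 and 125, were made with a stranded mRNA kit. The unit of these time points is not given in the sources used here, so they are named by number. This gave 36 libraries in 12 groups of 3.

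Per the submitters' processing notes, the reads were handled with Trimmomatic 0.36, STAR 2.5.2a, HTSeq 0.6.1p2 and R 3.5.2. The genome builds, the annotation and the strand setting of the counting are not given in the sources used here. Each of the 36 deposited files holds raw read counts for 52383 lines: 7268 S. pombe genes, 28006 human genes, 17104 fly genes and 5 summary lines of the counter. These counts were not normalised by the authors, as whole numbers with totals that differ between libraries show. The summary lines stayed out of library sizes and tests. Of all lines, reads without a feature made up 3.62 to 8.45% in labelled and 6.97 to 8.49% in steady-state libraries, and ambiguous reads 0.568 to 0.752% and 0.367 to 0.623%. Reads without a unique place made up 5.82 to 10.4% in labelled and 16.0 to 48.0% in steady-state libraries. The role of the human and fly RNA is not given in the sources used here. Human and fly genes entered only as totals per library.

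S. pombe totals ran from 921427 to 6517092 counts per library, with steady-state libraries holding fewer on the median than labelled ones. Symbols came from a table of the ASM294v3 assembly, which matched 6862 of the 7268 identifiers and gave a symbol for 4426; 5143 were protein coding. No coordinates are printed, because the build of the deposited counts is not known. Near-identical ribosomal protein paralogs can share reads, and overlapping and antisense genes cannot be separated without the strand setting, so values of such single genes are uncertain.

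Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM scaling, the filterByExpr filter at a minimum count of 10, and Benjamini-Hochberg adjustment with a threshold of 0.05. The genotypes were compared at steady state in the 6 libraries alone, and at each labelled time point in a fit of the 30 labelled libraries with 1 mean per group. Further contrasts were the difference between genotypes in labelled 5 over steady state (36 libraries), the difference between genotypes in the slope of labelled share on log2 of the time point (30 libraries), and WT labelled 5 against WT labelled 125 (36 libraries). The last was repeated in the knockout after the data had been seen. Log2 fold changes are knockout over WT, or labelled 5 over labelled 125. They describe shares of the S. pombe counts, not amounts per cell. Levels are TMM-scaled CPM from edgeR.

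The gene lists were fixed before the data were examined: 24 lists covering cytosolic ribosomal proteins, elongation and TOP-like factors, initiation factors, ribosome biogenesis, mitochondrial ribosomal proteins, the core environmental stress response, heat shock proteins, glycolysis and fermentation, hexose transporters, nitrogen starvation, the phosphate regulon, iron uptake, meiotic mRNAs, mating, auxotrophy markers, histones, the proteasome, the mitochondrial genome, oxidative phosphorylation, Tf2 retrotransposons, cytoplasmic mRNA decay, La and related proteins, small nuclear and nucleolar RNAs, and antisense and long non-coding RNAs. Lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. The lists of the mitochondrial genome and the Tf2 retrotransposons had at most 2 tested members in the fits of all 6 cultures and got no list test there; no member of either passed in those fits. Camera with an estimated correlation was run as an alternative, as was fry, which asks another question: whether the members of a list moved one way, without a comparison with other genes.

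Genes were named by a rule set before the data were examined: slr1, the 10 largest called changes each way among genes with a symbol, a mean of at least 10 CPM and, in comparisons of 3 against 3 libraries, no overlap between the groups, and of each list the 3 called members with the largest change, or the 2 with the smallest p where none was called. Genes outside this rule are said to have been chosen after their values were seen. The text does not describe each gene that met the rule. For WT labelled 5 against 125 it leaves out, among others, ipk1, rad26, bxi1 and laf1, higher at 5 with edgeR adjusted p between 0.0370 and 0.0429. It also leaves out tsp0 (−2.62), rpl4102 (−2.60) and rpl4302 (−2.43), lower at 5. Counts over named genes cover only the genes described.

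Other settings planned before the data were examined were DESeq2 1.42.0, limma-voom, RLE size factors, TMM factors without the ribosomal protein and elongation lists, no filter beyond 1 read, a filter of 5 CPM in 3 libraries, protein-coding genes only, other sets of libraries or time scales in the fit, a replicate block, and each culture left out in turn. Added after seeing the data were scaling to the human counts, a term for the set of cultures described with the libraries, and fits within each set.

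Libraries of 1 culture share that culture, so for contrasts within a genotype and for the contrasts of both fractions or of slopes the culture is a true block. Their deviations from the group means correlated at r = 0.222 or more between labelled libraries of a culture and at 0.167 or more between steady-state and labelled libraries, above a limit of 0.1. Replicate numbers do not pair the genotypes throughout. Across genotypes, 12 of 18 pairs with the same number lay above this limit. Pairs of numbers 2 and 3, each within 1 set of cultures, correlated at 0.121 to 0.702. Pairs of number 1, which lie in different sets, correlated at −0.541 to 0.0140. In the genotype comparisons at single labelled time points the culture could not be a block, because no culture holds both genotypes. Their fit treated the labelled libraries of a culture as independent. Its p-values, and those of the list tests there, can therefore overstate the replication.

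The tests at steady state, at labelled 5, of labelled 5 over steady state, of the trend and of WT labelled 5 against 125 were tried on counts simulated from the means, library sizes and dispersions of the data with the compared groups made equal, and with 100 genes changed at each size. At steady state 22% of genes changed 2-fold and 90% of those changed 4-fold were recovered among 5310 genes, with 11 false calls. For labelled 5 the shares were 44% and 82% among 5795 genes with 7 false calls, for labelled 5 over steady state 12% and 58% among 5808 with 6, and for WT labelled 5 against 125 42% and 84% among 5799 with 10. In the trend, 35% of genes with a slope difference of 0.25 and 79% of those with 0.5 were recovered among 5800 genes, with 3 false calls. With the ribosomal protein list raised 1.2-fold in simulated labelled 5 libraries, camera gave that list an adjusted p of 1.39e-08 and called 1 other list of 22. All simulated genes and libraries were drawn independently, with no effect of a culture or a set of cultures. In the data the members of this list had an estimated correlation of 0.524. The simulation therefore does not test the preset correlation, and its recovered shares and false calls ignore the sharing of cultures. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.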

Results

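The series measured mRNA in S. pombe by sequencing unselected RNA and RNA labelled with 4-thiouracil, in WT cultures and in cultures lacking slr1. Its title concerns the LARP1 homologue Slr1p and mRNAs resembling the 5'TOP mRNAs of other eukaryotes, which mostly encode ribosomal proteins and translation factors. There were 3 cultures per genotype, each giving 1 steady-state library and 5 labelled libraries. The libraries held between 921427 and 6517092 counts on S. pombe genes.

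The slr1 transcript (SPAC1527.03) separated the genotypes in each fraction. At steady state it reached 129 ± 18.1 CPM (SD, n = 3) in WT and 18.9 ± 6.34 CPM in the knockout, 14.7% of the WT level. In labelled RNA the WT means were 196 ± 51.9, 157 ± 37.5, 158 ± 66.3, 174 ± 33.2 and 180 ± 33.1 CPM at time points 5, 20, 50, 105 and 125 (SD, n = 3). The knockout means were 8.20 ± 7.85, 10.6 ± 5.26, 11.9 ± 2.08, 9.68 ± 1.27 and 10.4 ± 1.37 CPM, between 4.18 and 7.51% of WT. The value at time point 5 rested on knockout culture 2 (17.3 CPM, against 3.27 and 4.08 in cultures 1 and 3): without it the mean was 3.68 CPM, 1.87% of WT. Each knockout library lay below the lowest WT library of its fraction.

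**Figure D1:**
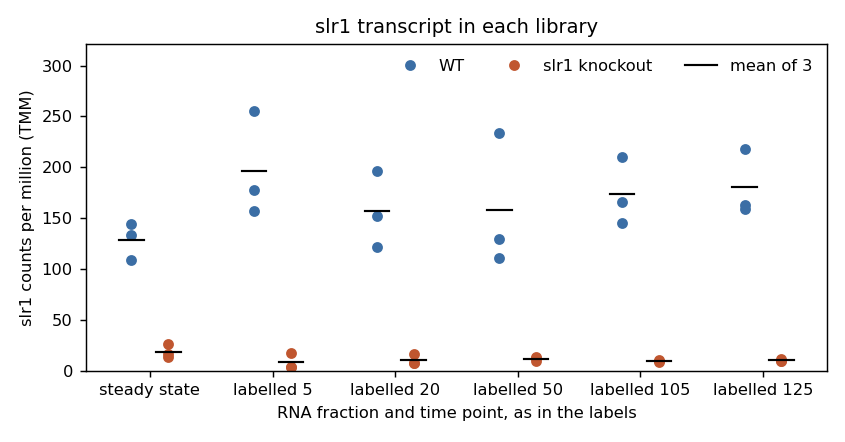
TMM-scaled CPM of slr1 in each of the 36 libraries, by RNA fraction and time point; points are libraries and bars the mean of 3. The knockout libraries lie between 3.27 and 26.1 CPM and the WT libraries between 109 and 255 CPM.

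The cultures fell into 2 sets that did not follow genotype. At steady state, fly counts per human count were 1.04 in WT culture 1, 0.990 in WT culture 2 and 1.07 in knockout culture 2, called set A here. They were 2.02 in WT culture 3, 2.15 in knockout culture 1 and 1.85 in knockout culture 3, called set B. In labelled RNA the ratio fell to between 0.00134 and 0.0330, and set A lay above set B at each time point. At time point 5 it was 0.00282 to 0.00698 in set A and 0.00134 to 0.00194 in set B. At 125 it was 0.0139 to 0.0330 in set A and 0.00228 to 0.00400 in set B. With genotype in the model, 693 of 5371 genes differed between the sets at steady state, 340 higher and 353 lower in set B. Values within each set are therefore given beside many of the pooled ones. Set A holds a single knockout culture and set B a single WT culture.

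**Figure D2:**
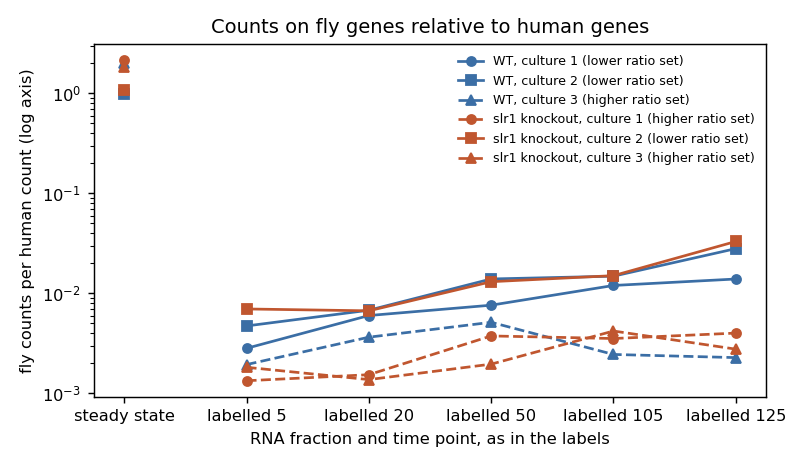
Fly counts per human count in each library on a log axis, by RNA fraction and time point, with lines joining the labelled libraries of a culture (solid for set A, dashed for set B). At steady state the values were 0.990 to 1.07 in set A and 1.85 to 2.15 in set B. In labelled RNA set A lay above set B at each time point.

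A comparison within WT asked which WT transcripts held a larger share of labelled RNA at time point 5 than at 125. Cytosolic ribosomal protein mRNAs were lower at time point 5: 115 of 140 passed the test, and the list median was −1.79 on the log2 scale. Among them were rpl4101 (−2.72, SE 0.50, adjusted p = 4.89e-04), rpl3802 (−2.66, SE 0.37, adjusted p = 2.14e-05), rps29 (−2.51, SE 0.39, adjusted p = 6.34e-05), rpl39 (−2.49) and rpp201 (−2.45). Outside that list, nxt2, a nuclear transport factor of the NTF2 family (−2.49, SE 0.31, adjusted p = 7.54e-06), and ppi1, a cyclophilin (−2.37, SE 0.45), were also lower at time point 5. Higher at time point 5 were vac7, a vacuolar regulator of phosphoinositide synthesis (1.06, SE 0.22, adjusted p = 0.00174), psu1 (1.05, SE 0.31), the splicing factor gene cwf20 (1.02, SE 0.30), zrg17, which encodes a zinc transporter (1.02, SE 0.16, adjusted p = 1.04e-04), rng10, a cytokinesis gene (0.95, SE 0.23), and ask1, of the DASH complex of kinetochores (0.92, SE 0.24).

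In total 121 genes were higher and 389 lower among 5823 tested, and 1337 had an unadjusted p under 0.05. With the culture as a block, 1154 were higher and 1178 lower, and the genes named here all passed. Within set A, 7 were higher and 81 lower; within set B, where 1 WT library stands against 1, 87 and 339. The total was 196 without WT culture 3 and 276 without WT culture 2. Scaled to the human counts, 0 genes were higher and 1383 lower, because the median of all genes moved from 0.08 to −0.95. In that scaling vac7 (−0.017), cwf20 (−0.030), rng10 (−0.044) and ask1 (−0.18) were no longer above 0, whereas psu1 (0.11) and zrg17 (0.014) were, and relative to the shifted median these 6 genes stood at 0.94, 0.93, 0.91, 0.78, 1.07 and 0.97. The ribosomal protein list stood at −1.83 relative to it, and at −1.87 relative to the median of the first scaling.

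Of the 140 ribosomal protein genes, 133 were lower when adjusted over the list alone and 136 with the culture block, where 1 was higher. The list median was −1.89 within set A and −1.48 within set B. Camera gave the list an adjusted p of 8.89e-81 with the preset correlation; the adjusted p = 0.0218 with an estimated correlation, and adjusted p = 0.0661 with an estimated correlation under the block. Of 14 elongation and TOP-like factors 8 were lower and 0 higher (10 and 1 adjusted over the list alone), with a median of −1.16. They included tef5, a subunit of the elongation factor 1 exchange complex (−2.03, SE 0.47, adjusted p = 0.00473), cpc2, the RACK1 homologue (−1.69, SE 0.42, adjusted p = 0.00936), and tif512, which encodes eIF5A (−1.58). Camera gave this list 1.84e-07, and adjusted p = 0.0637 with an estimated correlation; the median was −1.03 within set A and −1.07 within set B. Of 27 initiation factors 10 were lower (15 adjusted over the list alone), among them tif1, eIF4A (−1.38, SE 0.41), tif211, eIF2 alpha (−1.03, SE 0.20) and tif45, eIF4E (−0.97). Their median was −0.64 (−0.70 within set A, −0.52 within set B), with a camera adjusted p of 3.54e-10 and adjusted p = 0.0218 with an estimated correlation.

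mRNAs of oxidative phosphorylation were lower at time point 5 as well, with 16 of 44 passed (21 adjusted over the list alone) and a median of −0.84. The lowest named members were cox8 (−2.34, SE 0.34, adjusted p = 2.71e-05) and cox12 (−1.97, SE 0.26, adjusted p = 1.13e-05) of cytochrome c oxidase and qcr10 (−2.09, SE 0.42) of the cytochrome bc1 complex. The single member above 0 past the threshold was atp25 (0.61, SE 0.17), chosen after its values were seen, which moved to −0.45 in the human-count scaling and to 0.50 relative to its median. Camera gave the list 3.14e-11, with adjusted p = 0.0637 with an estimated correlation and 0.0476 so under the block; the medians within sets A and B were −0.92 and −0.62. Of 9 auxotrophy markers, leu1 (−1.64, SE 0.52) and ura5 (−1.17, SE 0.22, adjusted p = 7.45e-04), enzymes of leucine and pyrimidine synthesis, were lower (6 adjusted over the list alone). The median was −0.67 (−0.77 within set A, −0.51 within set B), with a camera adjusted p of 2.85e-04 and adjusted p = 0.428 with an estimated correlation. With the culture block 13 of 17 glycolysis and fermentation genes were lower against 0 without it; their median was −0.62, and camera gave 0.0507, or 6.16e-05 under the block with adjusted p = 0.351 with an estimated correlation.

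**Figure D3:**
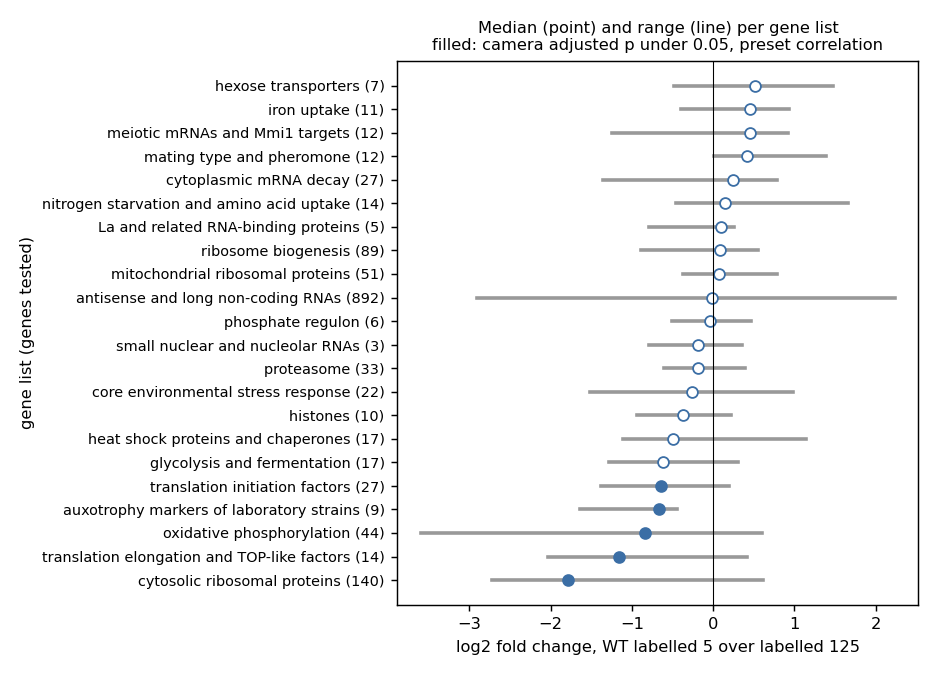
Median (point) and range (line) of the log2 fold change of WT labelled 5 over labelled 125 for each of 22 gene lists; filled points have a camera adjusted p under 0.05 with the preset correlation. Cytosolic ribosomal proteins lie lowest, at −1.79 in this scaling and −2.79 in the human-count scaling, where the 9 lists above 0 also lie below 0.

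The remaining lists held few called genes in edgeR with no culture block. Of 89 ribosome biogenesis genes, fib1, fibrillarin (−0.84, SE 0.19), and cbf5, the pseudouridine synthase of box H/ACA particles (−0.60, SE 0.16), were lower, and camera gave 0.962. Of 51 mitochondrial ribosomal protein genes, mrps12 (0.78, SE 0.22) and mrps26 (0.47, SE 0.15) were higher (camera 0.297); in the human-count scaling they stood at −0.30 and −0.56, and relative to its median at 0.65 and 0.40. Of 27 mRNA decay genes, lsm1 (−1.35, SE 0.35), lsm6 (−1.30, SE 0.31) and lsm5 (−1.18, SE 0.28), subunits of Lsm rings, were lower. The deadenylase gene ccr4 (0.64, SE 0.15), chosen after its values were seen, was higher, with −0.40 in the human-count scaling and 0.56 relative to its median; camera gave the list 0.513. Single members were lower in the core environmental stress response (gpx1, glutathione peroxidase, −0.98, SE 0.28; camera 0.223) and the proteasome (pts1, −0.50, SE 0.15; camera 0.196). Of 892 antisense and long non-coding RNAs 2 were higher and 6 lower (camera 0.870). They included SPNCRNA.1079 (1.49, SE 0.37) and SPNCRNA.862 (0.83, SE 0.23; −0.20 in the human-count scaling and 0.75 relative to its median), chosen after their values were seen, and SPNCRNA.1422 (−2.86, SE 0.53) and SPNCRNA.1666 (−2.57, SE 0.44). With the culture block more members passed: 7 higher and 13 lower in ribosome biogenesis, 8 and 1 in mitochondrial ribosomal proteins, 10 and 5 in mRNA decay, 1 and 5 in the core environmental stress response, 1 and 9 in the proteasome, and 68 and 82 among the non-coding RNAs.

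In edgeR with TMM scaling and no culture block, no member passed over all genes in the lists of heat shock proteins (median −0.50), hexose transporters (0.51), nitrogen starvation (0.14), phosphate (−0.04), iron uptake (0.45), meiotic mRNAs (0.45), mating (0.41), histones (−0.37), La and related proteins (0.09) and small nuclear and nucleolar RNAs (−0.18), nor for the 2 tested genes of the mitochondrial genome and the 2 of Tf2 elements. With the block members passed in most of these lists: heat shock proteins (8 lower of 17), hexose transporters (3 higher of 7), nitrogen starvation (2 higher of 14), phosphate (1 higher and 1 lower of 6), iron uptake (2 higher of 11), meiotic mRNAs (1 higher and 1 lower of 12), mating (5 higher of 12), histones (5 lower of 10) and La and related proteins (1 lower of 5). In the human-count scaling each of these positive medians fell below 0, and relative to its median those of hexose transporters, nitrogen starvation, iron uptake, meiotic mRNAs and mating stayed above 0 while that of the La list was −0.04. With the culture block camera called the lists of heat shock proteins (0.0223), histones (0.0470) and mating (0.0480), with adjusted p = 0.681, 0.681 and 0.139 with an estimated correlation. The 39 genes named for this comparison leave out some that met the naming rule. Of these 39, 16 passed with each single culture left out, among them rpl4101, rpl3802, rps29, rpl39, rpp201, nxt2, ppi1, zrg17, tif211, fib1, ura5, cox8, qcr10 and cox12. The other 23 lost the call without at least 1 culture of either genotype, as vac7 did without WT culture 2 (adjusted p = 0.0551) and tef5 without WT culture 3 (adjusted p = 0.0552). The highest adjusted p of the others was, without WT culture 3, 0.188 for psu1, 0.295 for cwf20, 0.137 for cpc2, 0.271 for tif1, 0.210 for tif45 and leu1, 0.259 for mrps12, 0.275 for gpx1, 0.211 for pts1, 0.0952 for lsm6, 0.289 for atp25 and 0.160 for SPNCRNA.862. It was, without WT culture 2, 0.114 for ask1 and tif512, 0.105 for ccr4 and 0.0814 for SPNCRNA.1079, and, without WT culture 1, 0.123 for rng10, 0.247 for mrps26, 0.101 for cbf5, 0.134 for lsm1 and 0.124 for lsm5. Leaving out a knockout culture also ended the calls of psu1, cwf20, mrps26, tif1, tif45, leu1, gpx1, pts1 and atp25. The fits with a culture left out, like those within a set, had no culture block. They do not show how the blocked test depends on single cultures. With the block and all cultures, edgeR gave vac7 and tef5 adjusted p = 2.50e-08 and 4.92e-10.

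The knockout cultures gave a similar picture of early and late labelled RNA. Of 140 ribosomal protein genes 113 were lower at time point 5 (131 adjusted over the list alone, 136 with the culture block), with a median of −1.82, −1.59 within set A and −1.98 within set B. Among these were rpl4101 (−3.12, SE 0.51, adjusted p = 1.18e-04), rps29 (−2.90, SE 0.39, adjusted p = 1.06e-05) and rpl39 (−2.85, SE 0.40). Also lower were tef5 (−1.91, SE 0.46), cpc2 (−1.75, SE 0.42), tif1 (−1.51, SE 0.41), tif45 (−1.17, SE 0.28) and cox8 (−2.15, SE 0.34). Higher at time point 5 were ght5, a high-affinity hexose transporter (2.61, SE 0.70, adjusted p = 0.0186; 0.84 within set A and 3.13 within set B), lcf2, a fatty acid ligase gene (1.24, SE 0.22, adjusted p = 2.92e-04), izh3 (1.13, SE 0.26), dcp1, of the decapping complex (1.12, SE 0.36, adjusted p = 0.0472), and zrg17 (1.01, SE 0.17). In WT ght5 was also above 0 (1.47, SE 0.68), past the threshold in edgeR only with the culture block (adjusted p = 0.190 without it and 0.00989 with it). Its slope difference between genotypes was −0.33 (SE 0.18), not past the threshold.

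In the knockout 127 genes were higher and 367 lower among 5823, with 1324 at an unadjusted p under 0.05. With the culture block 1145 were higher and 1017 lower. No gene passed within set A in edgeR, where 1 knockout library stands against 1 and 301 had an unadjusted p under 0.05, and within set B 619 were higher and 720 lower. The total was 104 without knockout culture 3 and 123 without knockout culture 1. Scaled to the human counts, 0 were higher and 465 lower, the median of all genes having moved from 0.08 to −0.64; the higher genes named for the knockout stayed above 0, between 0.04 and 1.95. The 16 genes named here also leave out some that met the naming rule. Of these 16, 7 passed with each single culture left out (lcf2, zrg17, rpl4101, rps29, rpl39, cox8 and ura5). Without knockout culture 3 the adjusted p was 0.307 for ght5, 0.218 for izh3, 0.426 for dcp1, 0.162 for tef5, 0.193 for cpc2, 0.276 for tif1 and 0.225 for pfk1, and without knockout culture 1 it was 0.263 for tif45 and 0.0929 for atp25. The calls of dcp1 and tif1 also ended without WT culture 3. Here too the fits with a culture left out or within a set had no culture block.

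Camera gave the ribosomal protein list 4.00e-91 in the knockout, and adjusted p = 0.0215 with an estimated correlation. Of 14 elongation and TOP-like factors 8 were lower (12 lower and 1 higher adjusted over the list alone), with a median of −1.23 and adjusted p = 0.0473 with an estimated correlation, or 0.0517 so under the block. Of 27 initiation factors 9 were lower (14 adjusted over the list alone), with a median of −0.63 and adjusted p = 0.0215 with an estimated correlation. Of 44 oxidative phosphorylation genes 12 were lower (19 adjusted over the list alone) and atp25 (0.81, SE 0.17), chosen after its values were seen, was higher; the median was −0.59, with camera 3.29e-08 and adjusted p = 0.158 with an estimated correlation, or 0.0486 so under the block. Of 17 glycolysis and fermentation genes pfk1, phosphofructokinase (−1.01, SE 0.27), was lower, and 15 with the block; the median was −1.01, with camera 8.24e-04 and adjusted p = 0.369 with an estimated correlation. Of 9 auxotrophy markers ura5 (−1.18, SE 0.22) was lower (2 adjusted over the list alone, 8 with the block), with camera 5.80e-04 and adjusted p = 0.369 with an estimated correlation. Members also passed in the lists of hexose transporters (1 higher of 7), mRNA decay (2 higher and 3 lower of 27), ribosome biogenesis (1 and 3 of 89), mitochondrial ribosomal proteins (1 and 1 of 51) and non-coding RNAs (2 and 7 of 892), none of which camera called. With the block members passed in more lists, among them ribosome biogenesis (11 higher and 11 lower), mRNA decay (14 and 4), mitochondrial ribosomal proteins (6 and 3), the proteasome (2 and 5), heat shock proteins (0 and 4), hexose transporters (4 and 0), mating (4 and 0), histones (0 and 3) and non-coding RNAs (45 and 48).

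Across the 5823 genes tested in both, the WT and knockout log2 fold changes correlated with r = 0.875 and rho = 0.847; genes are not independent replicates. There were 303 genes lower at time point 5 in both genotypes, where independent lists would share 24.5, and 57 higher in both, where they would share 2.64. No gene passed in opposite directions. With the culture block these numbers were 908 (206 for independent lists) and 815 (227).

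**Figure D4:**
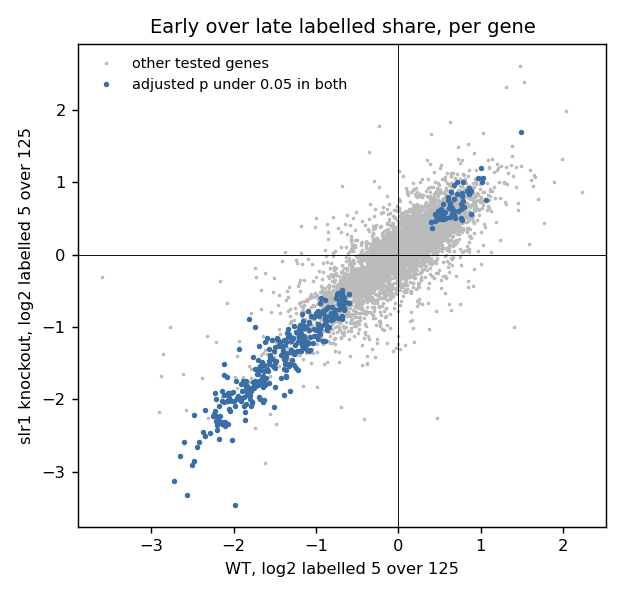
Log2 fold change of labelled 5 over labelled 125 per gene in WT (horizontal) and in the knockout (vertical); blue points passed in both. The blue points hold 303 genes below 0 and 57 above 0 on both axes; scaled to the human counts, 0 genes passed above 0 in either genotype.

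Relative to the same culture at steady state, the median ribosomal protein mRNA was under-represented in labelled RNA. The gap narrowed up to time point 105, changed little in the group means from 105 to 125, and was still below 0 at 125. In WT the median log2 ratio was −2.25 ± 0.18 at time point 5, −1.30 ± 0.23 at 20, −0.76 ± 0.24 at 50, −0.55 ± 0.14 at 105 and −0.57 ± 0.32 at 125 (SD, n = 3). In the knockout it was −2.27 ± 0.34, −1.75 ± 0.50, −0.83 ± 0.26, −0.46 ± 0.46 and −0.52 ± 0.27.

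**Figure D5:**
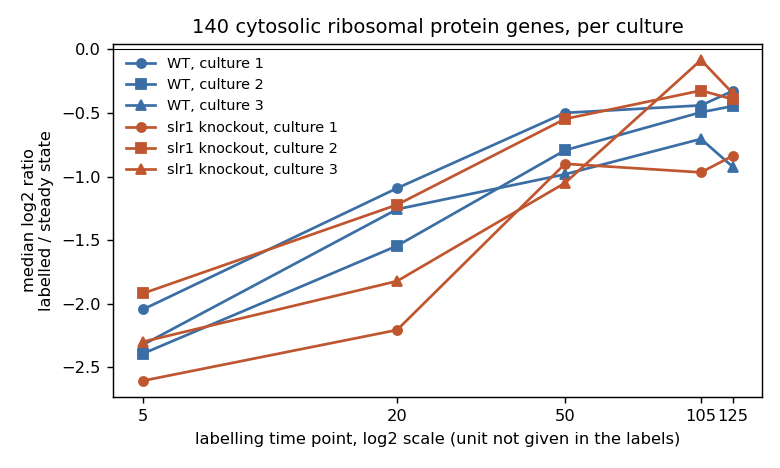
Median log2 ratio of labelled over steady-state share of 140 cytosolic ribosomal protein genes against time point (log2 scale, unit not given), with a line for each of 6 cultures. The lines of the genotypes overlap, from −2.61 to −1.92 at time point 5 and from −0.92 to −0.33 at 125.

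The next comparison asked what loss of slr1 did to RNA at steady state. Of 5371 genes tested, slr1 fell (log2 fold change −2.74, SE 0.29, adjusted p = 0.0218; −2.29 within set A and −3.13 within set B) and no other gene passed. Ribosomal protein mRNAs had a median of −0.05 with 0 of 140 past the threshold, and the named members rpp102 and rpl3702 stood at 0.49 (SE 0.32) and 0.50 (SE 0.38). Among 14 elongation and TOP-like factors none passed. Of these tef102, elongation factor 1 alpha, stood at 0.31 (SE 0.41), with 1.05 within set A and −0.31 within set B. The value for tef5 was −0.22 (SE 0.44), with −0.11 within set A and −0.03 within set B. Of the meiotic list mei2, an RNA-binding regulator of meiosis, stood at −1.35 (SE 0.50), short of the threshold. The stress response list had a median of −0.17 (0.19 within set A, −0.15 within set B; camera 0.00293), with rds1 at −0.65 (SE 0.31), oxidative phosphorylation −0.14 (−0.30 and 0.01; camera 0.0343), the La list, which holds slr1, −0.07 (−0.50 and −0.04; camera 0.00293), and non-coding RNAs 0.10 (0.08 and 0.07; camera 0.00293). With an estimated correlation none of these calls held: adjusted p = 0.931 for the first, second and last and 0.459 for the La list.

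At steady state 18 genes had an unadjusted p under 0.05, and 52 with the term for the set of cultures, where 269 would by chance. These counts lie far under chance, so the lack of other calls is weak evidence that nothing else changed. The slr1 call ended without any 1 of the WT cultures or of knockout cultures 1 and 3 (0 genes in edgeR). Its adjusted p was 0.116, 0.264 and 0.0532 without WT cultures 1, 2 and 3. It was 0.211 and 0.193 without knockout cultures 1 and 3. The ribosomal protein median was −0.20 within set A and 0.05 within set B, 0.25 without WT culture 2, −0.25 without WT culture 1, 0.01 without knockout culture 3 and −0.14 without knockout culture 1; the camera direction was up while the median was negative. Within set A 0 genes passed in edgeR and 30 had an unadjusted p under 0.05. Within set B, which holds a single WT library there, 7 passed, slr1 among them; the other 6 did not pass in the 6 libraries together.

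In labelled RNA slr1 was likewise the gene called between genotypes at each time point, among 5812 tested. Its log2 fold change was −4.45 (SE 0.42, adjusted p = 8.64e-07) at 5, −3.82 (SE 0.41, adjusted p = 1.14e-05) at 20, −3.70 (SE 0.42, adjusted p = 2.44e-05) at 50, −4.11 (SE 0.43, adjusted p = 6.64e-06) at 105 and −4.05 (SE 0.43, adjusted p = 6.39e-06) at 125. Within set A these were −3.60, −3.23, −3.85, −3.99 and −3.96, none past the threshold, and within set B −5.57, −4.34, −3.19, −4.18 and −4.04, all past it. No other gene passed in edgeR. At the 5 time points 62, 163, 74, 99 and 45 genes had an unadjusted p under 0.05, where 291 would by chance. With the term for the set of cultures they were 140, 383, 224, 148 and 121, above 291 at time point 20 alone. In each of these fits slr1 was still the 1 gene called. DESeq2 called a second gene at time point 20, nrg1, chosen after its values were seen (−2.77, DESeq2 adjusted p = 0.00959; edgeR −2.73, adjusted p = 0.375). At time point 5 the slr1 call ended when its 6 libraries were fitted alone (0 genes). The fit of all labelled libraries counted those of a culture as independent, so the adjusted p values given here can overstate the replication. The time points share their cultures and are not independent repeats of each other.

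No ribosomal protein mRNA passed between genotypes at any labelled time point, and the list medians depended on the set of cultures. At 5 the list median was −0.05 (0.18 within set A, −0.10 within set B; camera 0.207), with rps1401 at −0.62 (SE 0.51) and rpl4102 at −0.29 (SE 0.26), and eft202, elongation factor 2, at 0.19 (SE 0.33). At 20 it was −0.43 (0.02 and −0.67; camera 4.13e-32), with rpl4102 at −0.72 (SE 0.25) and rpl2501 at −0.57 (SE 0.19). At 50 it was −0.09 (0.02 and 0.02; camera 0.00140), at 105 0.10 (−0.03 and 0.25; camera 0.00104), with rpp102 at 0.58 (SE 0.26) and rps2502 at 0.58 (SE 0.28), and at 125 0.03 (−0.11 and 0.38; camera 0.00368), with rpl39 at 0.57 (SE 0.34). With an estimated correlation the calls were lost, with adjusted p = 0.233, 0.893, 0.858 and 0.823 from 20 to 125. At time point 5 the median was 0.18 without WT culture 2, −0.15 without WT culture 1, −0.21 without knockout culture 2, and 0.04 and 0.02 without knockout cultures 3 and 1. Single members changed sign between sets A and B: rps1401 at 5 (0.19 and −1.26), rps2502 at 105 (−0.28 and 0.70) and rpl39 at 125 (−0.39 and 0.76). The other genes named here kept their sign in both sets.

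mRNAs of oxidative phosphorylation had medians of −0.27 at time point 20, −0.17 at 50, −0.17 at 105 and −0.18 at 125 (camera 3.01e-06, 4.74e-05, 0.00914 and 0.00215; adjusted p = 0.233, 0.338, 0.853 and 0.810 with an estimated correlation). These medians were negative within both sets, between −0.15 and −0.09 in set A and between −0.26 and −0.03 in set B. Named members were qcr8 at −0.50 (SE 0.23) and atp15 at −0.39 (SE 0.18) at 20, qcr6 at −0.65 (SE 0.21) at 50, and atp18 at −0.69 (SE 0.23) at 50 and −0.61 (SE 0.23) at 125, subunits of the bc1 complex and ATP synthase, none past the threshold. Hexose transporters had medians of 0.47, 0.46 and 0.45 at 5, 20 and 50 (camera 1.78e-04, 1.03e-04 and 0.00177; adjusted p = 0.148, 0.230 and 0.287 with an estimated correlation), positive within both sets. Here ght5 stood at 1.68 (SE 0.70), 2.08 (SE 0.71) and 1.15 (SE 0.69), ght4 at 0.50 (SE 0.24) at time point 5 and 0.56 (SE 0.25) at 125, and ght1 at 1.08 (SE 0.47) at 20. For ght5 the value at time point 5 was −0.14 within set A and 2.47 within set B. At 20 it was 0.20 within set A and 2.76 within set B, and at 50 0.64 and 1.36.

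Antisense and long non-coding RNAs had medians of −0.21, −0.25, −0.25, −0.26 and −0.16 from time point 5 to 125 (881 tested, none passed; camera 9.94e-09, 1.41e-08, 9.29e-09, 2.90e-10 and 2.56e-07; adjusted p = 0.289, 0.233, 0.287, 0.294 and 0.632 with an estimated correlation). Within set A they were −0.05, −0.22, −0.12, −0.40 and −0.10, and within set B −0.24, −0.17, −0.11, 0.08 and −0.06. Other lists called by camera were the La list, which holds slr1, at 5 (0.00143; adjusted p = 0.0395 with an estimated correlation), 50 (0.00572; 0.122 so) and 125 (0.00220; 0.0505 so), heat shock proteins at 5 (median 0.30, 0.00591; 0.888 so) and 50 (0.27, 0.0268; 0.893 so), mitochondrial ribosomal proteins at 5 (−0.08, 0.0269; 0.422 so) and 20 (−0.11, 3.66e-04; 0.230 so), and ribosome biogenesis at 5 (−0.11, 0.0278; 0.888 so) and 50 (−0.12, 0.0146; 0.893 so). Glycolysis was called at 50 (0.27, 0.0298; 0.775 so) and 125 (0.26, 0.0142; 0.810 so), the stress response at 20 (−0.25; 0.512 so), and elongation and TOP-like factors at 20 (−0.04, 0.0443; 0.512 so) and 105 (0.24, 0.0360; 0.853 so), where tef101 stood at 0.49 (SE 0.34) and tma19, the TCTP homologue, at 0.43 (SE 0.31). Within sets A and B the heat shock medians were −0.02 and 0.01 at 5 and 0.13 and −0.0035 at 50, and the elongation medians 0.32 and −0.40 at 20 and 0.31 and 0.02 at 105. At 105 tef101 stood at 1.17 within set A and −0.18 within set B, and tma19 at −0.07 and 0.31.

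Scaled to the human counts, the median of all genes in the genotype comparisons moved to −0.29 at steady state and to 0.46, 0.11, 0.28, −0.35 and 0.13 at the 5 time points, and slr1 was still the gene called in each. The ribosomal protein list relative to these medians stood at 0.04, −0.03, −0.52, −0.06, 0.13 and 0.06, and on that scale itself at −0.24, 0.42, −0.41, 0.22, −0.22 and 0.18. The oxidative phosphorylation list at 50 and 125 turned to 0.15 and 0.03 on that scale, with −0.13 and −0.09 relative to the median, and the non-coding list at 5 turned to 0.26, with −0.19 relative to it. The medians of ribosome biogenesis at 5 and 50, of mitochondrial ribosomal proteins at 5 and of the La list at 5, 50 and 125 also turned positive there (0.29, 0.18, 0.38, 0.27, 0.04 and 0.08), and stayed negative relative to the median of all genes. So did rpl4102 at 5 (0.16, or −0.30 relative to it). Elongation factors at 105 turned to −0.10, the non-coding list at steady state to −0.18 and tef102 at steady state to −0.14, with 0.25, 0.10 and 0.15 relative to the median.

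The share of early labelled RNA over steady state was then compared between genotypes. No gene passed in edgeR among 5823, where 19 had an unadjusted p under 0.05 and 291 would by chance. DESeq2 called 0 with 18 and limma-voom 0 with 26. The ribosomal protein median was 0.03 (0.34 within set A, −0.12 within set B; camera 0.159, with direction down), and it was −0.07 without WT culture 2 and −0.13 without knockout culture 2. Of its members ubi3, a ubiquitin and ribosomal protein fusion, stood at −0.54 (SE 0.40) and rps1401 at −0.93 (SE 0.75). Within sets A and B ubi3 stood at 0.03 and −0.54, and rps1401 at −0.58 and −1.64. The stress response list had a median of 0.23 (−0.29 and 0.54 within sets A and B), with camera 0.0382 and adjusted p = 0.755 with an estimated correlation. Its members gld1, glycerol dehydrogenase, and ntp1, trehalase, stood at 1.39 (SE 0.94) and 0.72 (SE 0.41). Within sets A and B gld1 stood at 1.15 and 1.96, and ntp1 at −0.20 and 1.36. The 892 non-coding RNAs had a median of −0.24 (−0.09 and −0.35 within the sets), with camera 6.02e-11, adjusted p = 0.449 with an estimated correlation and 0.0878 so with the culture block. In the human-count scaling the median of all genes was 0.75, the non-coding list stood at 0.52 and ubi3 at 0.0020, and relative to the median these were −0.24 and −0.75. With the culture block 0 genes passed and 211 had an unadjusted p under 0.05, and camera called 5 further lists, none of which held with an estimated correlation: their adjusted p values were between 0.603 and 0.629.

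The last comparison asked whether transcripts gained labelled share with time at another rate without slr1. No gene passed in edgeR among 5812, where 33 had an unadjusted p under 0.05 and 291 would by chance. DESeq2 called 0 with 40 and limma-voom 0 with 32, and the culture block 0 with 159. The ribosomal protein list had a median slope difference of 0.045 per doubling of the time point, −0.036 within set A and 0.13 within set B, with rps1702 at 0.14 (SE 0.066) and rps1401 at 0.23 (SE 0.12). Without knockout culture 3 the median was 0.00402. Camera gave it 5.05e-15, which was lost with an estimated correlation (adjusted p = 0.526). Fry, which asks whether the members moved one way and not whether they differed from other genes, gave 0.990. Per culture, the median slope of the list was 0.369 ± 0.0534 in WT and 0.424 ± 0.0767 in the knockout (SD, n = 3; exact permutation p = 0.5, two-sided, 0.88 adjusted over 22 lists, where 3 against 3 cannot give less than 0.1). The slopes of the genotypes did not overlap in elongation and TOP-like factors (0.202 ± 0.0245 in WT, 0.283 ± 0.0648 in the knockout) and in glycolysis (0.121 ± 0.0354 and 0.190 ± 0.0193), each at the smallest possible p of 0.1 and 0.88 adjusted; these were 2 of the 22 lists, and chance alone separates 10% of lists so. Within sets A and B the median slope differences were −0.010 and 0.071 for elongation and TOP-like factors and 0.12 and 0.066 for glycolysis. Camera also called elongation and TOP-like factors (0.043; 0.00902), with tef101 at 0.10 (SE 0.081), glycolysis (0.090; 0.00697), mitochondrial ribosomal proteins (0.016; 0.0431), iron uptake (−0.0067; 0.0431) and oxidative phosphorylation (−0.0086; 0.0431), none of which held with an estimated correlation (adjusted p = 0.526 or 0.927). In the human-count scaling the median of all genes was −0.10 and the ribosomal protein, elongation and mitochondrial ribosomal protein lists stood at −0.034, −0.048 and −0.079, or 0.070, 0.056 and 0.025 relative to it.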

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

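The tests of a mislabelled culture, of the scaling and the uneven sets in the labelling trend, of length and uridines in WT labelled RNA, and all values within or adjusted for the sets of cultures were chosen after the result was seen. In the share of early labelled RNA over steady state, the genotypes differed by camera in the core environmental stress response (0.23) and in antisense and long non-coding RNAs (−0.24). In the labelling trend they differed in ribosomal proteins (0.0448), elongation and TOP-like factors (0.0428), mitochondrial ribosomal proteins (0.0158), glycolysis and fermentation (0.0898), iron uptake (−0.00668) and oxidative phosphorylation (−0.00862). None of these list differences was called with an estimated correlation. Counts of other organisms, which no comparison tested, were above the floor of 3 counts: at least 182 fly counts in each labelled library and at least 92935 human counts in each of the 36 libraries.

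Single genes of several lists differed between the 2 sets of cultures at steady state. The stress response list was called with the preset correlation (median −0.37, 5 of 22 lower; camera 0.00651), as were iron uptake (−0.79; 0.0256), mating and pheromone genes (−0.56; 0.0398) and, higher in set B, the proteasome (0.23; 0.0398). With an estimated correlation none of these 4 was called (adjusted p = 0.615, 0.702, 0.615 and 0.858). With genotype in the model, 693 of 5371 genes differed, among them fbp1, of gluconeogenesis (−4.40 in set B relative to set A), the sulfiredoxin gene srx1 (−1.81) and isp6 (−1.95), lower in set B, and nop10, of ribosome biogenesis (1.25), higher. Genes higher in set B were shorter (median 1035 bases) than genes lower in it (2054), yet after a smooth trend on transcript length the called genes kept a ratio of 0.890 of their log2 change, which argues against length as the whole cause. A mislabelled genotype is argued against by slr1, since 0 knockout libraries lay above the lowest WT library of their fraction. Growth state, a difference in handling or library preparation, and added RNA remain open, and no biological explanation was tested.

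In the fitted slope, the ribosomal protein list stood 0.0448 higher per doubling of the time point in knockout cultures. Its medians between genotypes at single time points did not rise steadily: −0.05, −0.43, −0.09, 0.10 and 0.03 from 5 to 125. The list medians of labelled 5 over 125 were alike, −1.79 in WT and −1.82 in the knockout. On the human-count scale itself the slope difference was −0.0342. Under 3 other scalings the list lay at least 0.0384 above the median of all genes. A factor per library shifts all genes alike, so such a relative value can hardly test scaling and decides nothing about it. With a term for the sets the list median was 0.0487. The standard error between cultures of 0.0539 is as large, so the uneven sets cannot be told apart from an effect of slr1. Within set A the value was −0.0362 and within set B 0.128, and without knockout culture 3 it was 0.00402. An effect of slr1 on these mRNAs may exist, but the data do not separate it from the spread between cultures.

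Ribosomal protein mRNAs held a lower share of early than of late WT labelled RNA. In the fit with the culture as a block, the list lay at −1.43 relative to genes matched on length (SD of the matched genes 0.715) and at −1.41 relative to genes matched on uridines (SD 0.697), and 138 of 140 members lay below their matched genes. These values argue against length or uridine number as the whole cause. A slow turnover of these mRNAs may give such a pattern, as may a pull-down that loses some RNAs, and neither was tested by an independent value.

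The 6 cultures make 10 splits into groups of 3, too few for a share under 0.05. For the genotype counts, the real split called 1 gene at steady state (2 of the 10 splits gave as many or more; highest other 1020), and 1 at time points 5 (2; 665), 20 (3; 909), 50 (2; 483), 105 (2; 1283) and 125 (2; 896). In each case the highest was the split by set, which points to a structure of the samples; within set A the genotype counts were 0 in edgeR and within set B 7 and then 1 each. For labelled 5 over steady state and for the trend the real split called 0 genes in edgeR (19 and 33 at an unadjusted p under 0.05; 0 also by DESeq2 and limma-voom), so 10 of 10 splits gave as many, with 3 and 0 as the highest other; the 3 came from the split by set. For the size of the ribosomal protein median the numbers were 0.05 at steady state (9 of 10; 0.43), 0.05 at time point 5 (7 of 10; 0.42), 0.03 over steady state (10 of 10; 0.35) and 0.04 in the trend (5 of 10; 0.10). Of these the split by set gave 0.06, 0.23, 0.17 and 0.03. The genotype comparisons called 37 other lists (8 of 10; 69; split by set 44). For time points 5 and 125 the real split called 510 genes in WT and 494 in the knockout, and no other split gave as many (1 of 10; highest other 0). The ribosomal protein median was 1.79 in size there (1 of 10; 1.03, and 0.87 for splits that part 3 pairs); the other splits mix both time points in each group.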

How the results depend on the processing

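Human-count scaling, the term for the set of cultures, the fits within sets A and B, and the knockout comparison of time points 5 and 125 with its alternatives were chosen after the result was seen. For counts, lists and the slr1 level, 244 alternative values were the same, 38 moved, 8 reversed, 8 became stronger and 3 weaker. A ribosomal protein list median was the same if it kept its direction and side of the threshold. A count was the same if within a fixed ratio of the main count, as the WT counts of 510 and 694 (DESeq2) were. The slr1 level was the same if within the SD of the knockout level. Genotype counts were mostly 1 (slr1) or 0 in both fits, which scores as the same. For 98 named genes by comparison, 1662 of 1897 values were the same, 209 weaker, 16 moved, 1 stronger and 9 reversed. A gene was the same if it kept its sign and its side of the threshold. A gene called in neither fit was also the same if its sign changed by less than its SE. Genes not called between genotypes thus met an easy rule, so the tally does not measure how firm calls are. The ribosomal protein result between WT time points 5 and 125 kept its direction and call under each alternative taken singly, and its call ended (adjusted p = 0.0661) where the culture block and an estimated correlation were combined. The steady-state count of 1 was 0 with the replicate number as a block (which does not pair the genotypes: r between −0.541 and 0.702), 0 within set A, 7 within set B, and 0 to 1 with a culture left out. Within set A the count was 0 at each labelled time point; it was 0 at time point 5 in its 6 libraries alone and 2 at 20 with DESeq2. The WT count of 510 was 2332 with the culture as a block, 1050 with the set term, 1383 with human-count scaling, 88 within set A, 119 in the 6 libraries alone and 196 to 605 with a culture left out. The knockout count of 494 was 2162 with the block, 868 with the set term, 0 within set A, 1339 within set B and 104 to 606 with a culture left out. The ribosomal protein median was, at steady state, 0.051 within set B and −0.25 to 0.25 with a culture left out. At time point 5 it was −0.056 with coding genes only, 0.029 with the set term, 0.42 with human-count scaling, 0.18 within set A, −0.10 within set B and −0.21 to 0.18 with a culture left out. Over steady state it was 0.012 with coding genes only, −0.029 with the culture block, 0.34 within set A, −0.12 within set B and −0.13 to 0.15 with a culture left out. In the trend it stayed 0.0448 but was no longer called with an estimated correlation or by fry (which does not compare a list with other genes), and was −0.0342 with human-count scaling, −0.0362 within set A and 0.00402 to 0.0849 with a culture left out. Of 41 calls of other lists, 2 were made with an estimated correlation and 6 by fry, and 37 to 68 with a culture left out. Between genotypes, the La list was the only list called by camera with an estimated correlation (time point 5, 0.0395) or by fry (5, 0.00589, and 125, 0.0189). It holds slr1 among 5 members, so the knockout itself moves it. No list without slr1 was called so between genotypes. The other such calls were in WT labelled 5 against 125. With human-count scaling vac7 (−0.0174), cwf20 (−0.0295), rng10 (−0.0442), ask1 (−0.18), mrps12 (−0.30), mrps26 (−0.56), atp25 (−0.45), ccr4 (−0.40) and SPNCRNA.862 (−0.20) reversed, none of them past the threshold there. Fits with fewer cultures test fewer libraries and had no culture block. A lone culture in a set is assumed to vary like the others. The cause of the changes was not tested. The steady-state test recovered 22% of simulated 2-fold changes; depth, spread between cultures and group size were not varied apart.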
